A study of Caenorhabditis elegans with 2 samples.

How the data were processed

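Chromatin immunoprecipitation followed by sequencing (ChIP-seq) of LSY-2, a C2H2 zinc finger transcription factor, was measured in whole Caenorhabditis elegans larvae at the L2 stage. Per the labels, the animals were of the strain OP367, which carries an integrated transgene (wgIs367) expressing LSY-2 with a GFP-FLAG tag at its C terminus in the unc-119(tm4063) background, and chromatin was sheared by sonication. The series held 1 group with 2 biological replicates and 1 library each. With 1 group, the design gave no comparison between conditions, and the comparisons were between the replicates and between parts of the genome. Whether the replicates came from separate cultures was taken from the labels, which call them biological replicates.

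Per the file descriptions deposited with the samples, the authors called a relaxed peak list on each replicate against a control library, a relaxed list on both replicates pooled, and an optimal list that was derived from these by the irreproducible discovery rate (IDR) procedure. The peak caller, the aligner and the IDR threshold were not given in the sources used here. Each list was given on the builds ce11 and ce10, which made 8 peak lists in all. The control reads were not analysed here.

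Each peak carried a signal score that the authors' peak caller gave it; the scale of this score was not given in the sources used here. The score is therefore the authors' own value per peak. It was used to rank, describe and compare peaks within a list and to compare matched peaks between the replicates. With the scale unknown, a ratio of scores between replicates is no measure of a difference in binding. The lists also held the −log10 of a q-value that the authors deposited for each peak. It was at its maximum of 4.26 for 100% of the optimal peaks on ce11, so it could not rank them. The relaxed lists each held 30000 peaks, and the 6312 optimal peaks on ce11 were the 6312 pooled peaks with the highest scores. Because the files used here hold no read counts, the sequencing depth of the libraries is unknown, and no interval that needs it was computed. Intervals given for shares of peaks or genes are exact Clopper-Pearson 95% intervals and cover the counting of peaks or genes only.

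Positions were taken on ce11, which is the assembly WBcel235, and the ce10 lists were used for peak counts and for the overlap and the score correlation of the replicates. Genes and transcripts came from Ensembl annotation release 115 and gene symbols from RefSeq annotation of the same assembly, matched by WormBase gene identifier for 46881 of 46890 genes. A promoter was the stretch from 1000 bp upstream to 200 bp downstream of the 5′ end of a protein-coding gene. A gene had a promoter peak when an optimal summit lay in its window, so a peak between divergent genes counted for both. Summits matched between lists when they lay within 200 bp of each other. Where replicates were compared, the same number of peaks was taken from each relaxed list, the 6312 with the highest scores.

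Chance values came from 1000 circular shifts of the summits within each chromosome. Those for the bins of distance from a 5′ end came from fewer shifts and gave no p. The smallest p that 1000 shifts can give is 0.001 in a one-sided test and 0.002 in a two-sided test. Median scores were compared by a two-sided permutation test with 100000 resamples, whose smallest p is 1e-05. Shares of peaks on X and in the middle sections of autosomes were tested by two-sided exact binomial tests after summits within 1000 bp of each other had been merged. The 21 gene lists and the 123 gene name classes with 15 or more members were tested by two-sided Fisher exact tests against all other protein-coding genes, with Benjamini-Hochberg adjustment over lists or over classes; odds ratios have 0.5 added to each cell. Annotated gene types with 50 or more genes were tested by the shifts, with a gene counted when a summit lay within 200 bp of it. For 6-mers, with reverse complements joined, the 101 bp around each summit were compared with a window of the same size 300 bp away on a randomly drawn side, by an exact McNemar test with Benjamini-Hochberg adjustment over 2080 6-mers. An adjusted p below 0.05 counted as a call. Because peaks and genes are not independent biological replicates, these p-values describe these lists.

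The gene lists, the tests and the rule for named genes were fixed before the data were examined. The rule named the gene with the nearest 5′ end within 2000 bp of each of the 20 strongest peaks, the up to 3 members with the strongest promoter peak in each list of up to 40 members, the 2 strongest in each larger list, and lsy-2, lsy-6, cog-1, die-1, lim-6, fozi-1, gcy-5, gcy-7 and unc-119 in any case. The list symbols lsy-15, rla-0, rla-1 and rla-2 matched no symbol and were left out, while daf-21 was tested under its current name, hsp-90. The 6-mer ACCGTA and genes named outside the rule were chosen after their values were seen.

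Alternatives covered each replicate's list in place of the optimal list, the strongest 50% of the optimal list, wider and narrower promoter windows, the 5′ ends of all transcripts, assignment to the nearest gene only, the distance to the next gene upstream as a covariate in a logistic model, other matching distances, ce10, other expected shares and other 6-mer windows. The functions were tested on simulated data. With 30 genes per list and 60% of them given a peak, 10 of 10 planted lists and 1 of 200 unplanted lists were called among 19973 genes. A 6-mer planted in 10% of simulated windows was recovered among 2080 tested, with 6 other 6-mers called. These windows lay at random places in the genome, so summits and flanks had like base composition, unlike the real ones. The simulation therefore does not show how many calls in the real windows follow from base composition. The work used Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.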

Results

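LSY-2 binding was mapped in L2 larvae in 2 biological replicates of whole animals. LSY-2 is known for its role in the left-right asymmetry of the ASE taste neurons, where it acts upstream of the microRNA gene lsy-6. The tag on LSY-2 allowed the protein to be pulled down from the whole animal, so the peaks are a mixture over all cells that expressed the transgene. The authors' optimal list held 6312 peaks on ce11, with scores from 58.0 to 20472 and a median of 123. No read depth could be given for either library.

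The 20 strongest LSY-2 peaks all lay at promoters, and none ranked below 23 in replicate 1 or below 20 in replicate 2. The peak with the highest score, 20472, lay at chromosome III 3867138 to 3867880, with its summit 283 bp upstream of rpl-3, which encodes a protein of the large ribosomal subunit. It ranked 1 in replicate 1 and 1 in replicate 2. Next were a peak with a score of 19393 between Y17G9B.5 and rpl-18A on chromosome IV and a peak with a score of 15628 upstream of cox-5A, which encodes a cytochrome c oxidase subunit, on chromosome III. The genes nearest to the 20 peaks also included rpl-15, rps-3A, rpl-11.2, the elongation factor gene eef-2, the actin capping gene cap-2, the replication factor gene rfc-4, the dishevelled gene mig-5 and the DRM complex gene lin-9. The remaining ones were F55A11.1, Y55F3AR.2, ekl-4, nra-2, Y25C1A.8, serp-1.1, ndub-8, elof-1 and dpm-3.

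The replicates shared most of their strong peaks. Of the 6312 strongest peaks of replicate 1, 5072 (80.4%, 95% interval 79.4 to 81.3) had a summit within 200 bp of a summit among the 6312 strongest of replicate 2. Shifted summits gave 2.63% ± 0.214 (SD over 1000 shifts), and the one-sided circular-shift permutation p was 0.001, the smallest the shifts can give. Among the 500 strongest peaks of each replicate the share was 91.6%, and among the 20000 strongest it was 64.9%. Across 4989 matched peaks the scores of the replicates had a Spearman correlation of 0.898 (95% interval 0.892 to 0.903), which is across peaks and not across independent samples. The median distance between matched summits was 19 bp. Of the optimal peaks, 5004 (79.3%) were found among the 6312 strongest of both replicates and 105 (1.66%) in neither. Of the weakest 10% of the optimal list, 9.02% were among the strongest of both replicates, against 99.8% of the strongest 10%. The optimal list is the 6312 highest pooled scores, so its weakest peaks lie near the cutoff and this contrast follows partly from the ranking. In the whole relaxed lists of both replicates, 6222 of the optimal peaks (98.6%) had a summit within 200 bp. The optimal list was derived from these same replicates, so its support in them was partly built in.

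**Figure D1:**
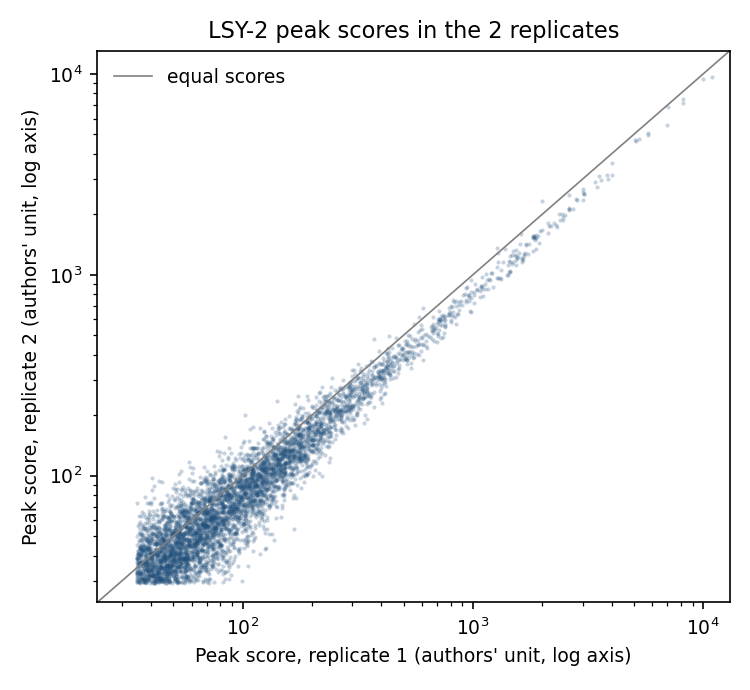
Scores of 4989 peaks matched between the 6312 strongest peaks of replicate 1 (horizontal, log axis) and of replicate 2 (vertical, log axis), in the authors' unit; each point is a peak and the line marks equal scores. The points follow a line with a Spearman correlation of 0.898, and the median ratio of replicate 1 to replicate 2 was 1.21.

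LSY-2 peaks gathered just upstream of genes. Of the 6312 summits, 3054 (48.4%, 95% interval 47.1 to 49.6) lay in a promoter of a protein-coding gene, against 21.2% of shifted summits (one-sided circular-shift permutation p = 0.001, the smallest the shifts can give). Each summit was counted once, with promoters first, then 5′ UTRs, coding exons, 3′ UTRs, introns and the rest. The other shares therefore leave out all sequence in promoter windows, which includes exons and 5′ UTRs near a 5′ end. Outside promoters, coding exons held 67 summits (1.06%), against 19.9% by chance, and introns held 1458 (23.1%), against 31.4%. The two-sided circular-shift permutation p was 0.002 for each, the smallest possible. Summits in intergenic sequence made up 22.6%, against 21.1% by chance (permutation p = 0.00999). The share in 5′ UTRs outside promoter windows, 0.982%, did not differ detectably from 0.820% (permutation p = 0.194). The 3′ UTRs held 1.14% of summits, against 2.41% by chance (permutation p = 0.002). Of the 4390 summits within 2000 bp of a 5′ end, 75.9% lay upstream of it, and the fullest bin, from -200 to -100 bp, held 802 summits, against 118 by chance.

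**Figure D2:**
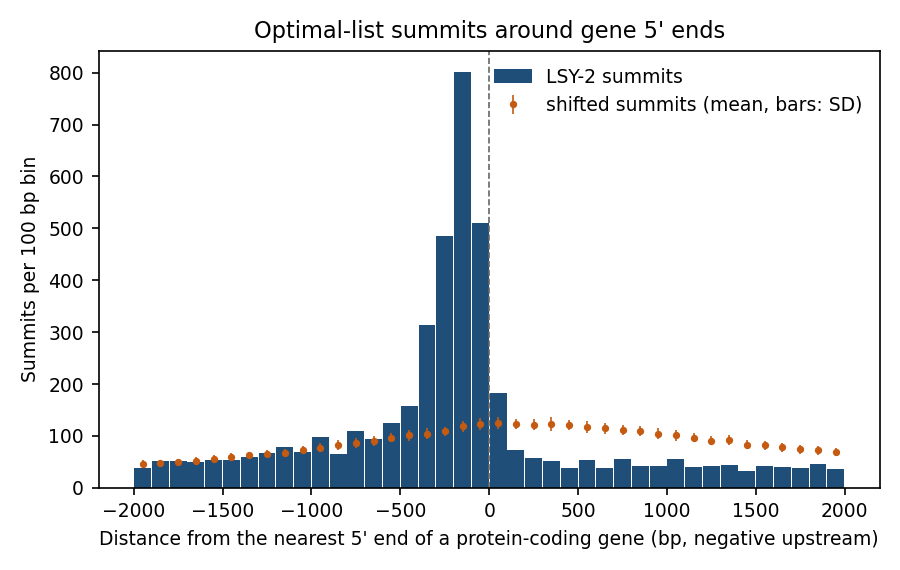
Number of optimal summits per 100 bp bin (vertical) by distance from the nearest 5′ end of a protein-coding gene in bp (horizontal, negative upstream); bars are LSY-2 summits and points are means of shifted summits with their SD. The bin from -200 to -100 bp held 802 summits, against a chance mean of 118.

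Promoter peaks were stronger than the others. The median score was 174 for the 3054 promoter peaks and 99.4 for the 3258 others, a ratio of 1.75 (two-sided permutation p = 1e-05, the smallest it can give). The promoter share rose from 31.3% in the weakest 10% of peaks to 81.1% in the strongest 10%. The median distance from the nearest 5′ end was 1624 bp in the weakest 10% and 240 bp in the strongest 10%.

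Over the chromosomes, peaks were densest on III, with 93.2 per Mb, and thinnest on V, with 41.3 per Mb. X held 889 of 5631 merged peaks (15.8%, 95% interval 14.8 to 16.8), which was below its 17.7% of the genome length (exact binomial p = 0.000184) and above its 13.7% of protein-coding genes (p = 6.14e-06). The direction of the X difference therefore depended on what it was set against. With the strongest 50% of peaks the X share was 12.7% (95% interval 11.6 to 13.99), below its share of length, and the interval included its share of genes. In the middle sections of the autosomes, which make up 33.3% of their length, lay 2093 of 4742 merged autosomal peaks (44.1%, exact binomial p = 8.6e-54). These sections held 38.1% of autosomal gene 5′ ends, and the share of peaks was also above that value (exact binomial p = 2.39e-17).

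Ribosomal protein, proteasome and respiratory chain genes had promoter peaks more often than other genes. Of 19973 protein-coding genes, 3831 (19.2%) had a promoter peak. Among ribosomal protein genes the count was 70 of 78 (odds ratio 35.6, Fisher exact test with Benjamini-Hochberg adjusted p = 1.79e-40), led by rpl-3 and rpl-18A. Among proteasome genes it was 27 of 32 (odds ratio 21.2, Fisher adjusted p = 2.06e-14), with scores of 4716 at pas-4, 4420 at rpn-5 and 1838 at rpn-13. Genes of the respiratory chain had a peak in 17 of 26 cases (odds ratio 7.79, Fisher adjusted p = 1.38e-06), with cox-5A, atp-1 and cox-5B strongest. This list rests on the names nuo, cox and atp alone and leaves out genes with other names, such as ndub-8. Chaperone genes had a peak in 18 of 33 cases (odds ratio 5.05, Fisher adjusted p = 2.2e-05), led by cct-8, cct-1 and hsp-60. When each peak was given to its nearest 5′ end only, the ribosomal count was 41 of 78 (odds ratio 6.60) and the proteasome count 20 of 32 (odds ratio 9.73), and both still passed (Fisher adjusted p = 3.23e-14 and 4.07e-09). The peaks at cct-8 and cct-1 lay between divergent genes, and with that assignment the chaperone count was 8 of 33 and the list no longer passed (odds ratio 1.97, Fisher adjusted p = 0.232).

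Several lists of developmental genes also had more promoter peaks than other genes. The synMuv B and DRM genes, which include the worm retinoblastoma gene lin-35, had a peak in 9 of 16 cases (odds ratio 5.35, Fisher adjusted p = 0.00322). The strongest were at lin-53 with a score of 9756, lin-9 with 6939 and lin-54 with 1719, and the lin-53 peak was shared with the divergent gene nra-2. The heterochronic genes, which time larval development, had a peak in 6 of 11 cases (odds ratio 4.99, Fisher adjusted p = 0.0198), with scores of 1212 at puf-9, 696 at lin-46 and 338 at lin-28. With the narrower promoter window this list did not pass (Fisher adjusted p = 0.117). Of its microRNA members, which were described and not tested, lin-4, mir-48 and mir-241 had a promoter peak, with scores of 82.5, 220 and 258, while let-7 and mir-84 had none.

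Hox and Wnt genes had a peak in 9 of 19 cases (odds ratio 3.82, Fisher adjusted p = 0.0116), with ceh-13, sys-1 and nob-1 strongest. The Hox genes with a peak were ceh-13, lin-39, mab-5, egl-5 and nob-1, and php-3 had none. Among Wnt pathway genes lin-17, pop-1, pry-1 and sys-1 had a peak. The others had none, including the ligand genes egl-20, lin-44, cwn-1, cwn-2 and mom-2. Hox genes and Wnt genes were not tested apart, so the call does not hold for Wnt genes by themselves. Pan-neuronal genes had a peak in 10 of 21 cases (odds ratio 3.85, Fisher adjusted p = 0.00771), with ric-19, snb-1 and syd-2 strongest. Body wall muscle genes had a peak in 9 of 21 cases (odds ratio 3.21, Fisher adjusted p = 0.0209), with hlh-1, act-2 and act-4 strongest. These 3 lists did not pass when the strongest peaks of replicate 1 alone were used, with Fisher adjusted p of 0.13, 0.0936 and 0.24. The Hox and Wnt list also failed with the strongest 50% of peaks (Fisher adjusted p = 0.432) and the narrower window (adjusted p = 0.271), and the muscle list with the strongest 50% of peaks (adjusted p = 0.88). With the wider promoter window the pan-neuronal and muscle lists each had a peak in 15 of 21 cases (odds ratio 7.27).

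Chemoreceptor genes, which are expressed mainly in sensory neurons, almost never had a promoter peak. The count was 8 of 1053 (0.76%, odds ratio 0.0321, Fisher adjusted p = 9.18e-85), with srh-16 and sri-5 strongest, and 20 with the wider promoter window (odds ratio 0.0564). F-box and BTB genes had a peak in 26 of 395 cases (odds ratio 0.297, Fisher adjusted p = 4.91e-12), with bath-42 and fbxc-23 strongest. Nuclear receptor genes had a peak in 37 of 269 cases (odds ratio 0.676, Fisher adjusted p = 0.0411), with nhr-47 and nhr-142 strongest. That call was lost with the strongest peaks of replicate 2 alone (Fisher adjusted p = 0.165), with the nearest 5′ end only (adjusted p = 0.667) and with the 5′ ends of all transcripts (adjusted p = 0.0654). With the strongest 50% of peaks the odds ratio was 0.364 (Fisher adjusted p = 5.44e-05).

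The other 9 lists did not pass the test. They were neuronal identity regulators (2 of 25, unc-42 and unc-30), germline genes (2 of 34, spo-11 and prg-1, Fisher adjusted p = 0.0794), histone genes (12 of 72, with his-37 and his-68 strongest), intestine genes (1 of 16, elt-2), epidermis genes (3 of 24, dpy-10, nhr-23 and nhr-25), ciliated neuron genes (4 of 19, with daf-10, daf-19 and bbs-9 strongest), pharynx genes (1 of 9, eya-1), homeobox genes (8 of 64, with ceh-38 and ceh-20 strongest) and the ASE asymmetry genes. The homeobox list took only genes named ceh, so homeobox genes with other names, such as lin-39 and mab-5, were left out. Homeobox genes as a whole family were therefore not tested. The germline list passed with the wider promoter window (Fisher adjusted p = 0.0148). It also passed in the logistic model with the distance to the next gene as a covariate (likelihood ratio test, n = 19973 genes, adjusted p = 0.0406).

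**Figure D3:**
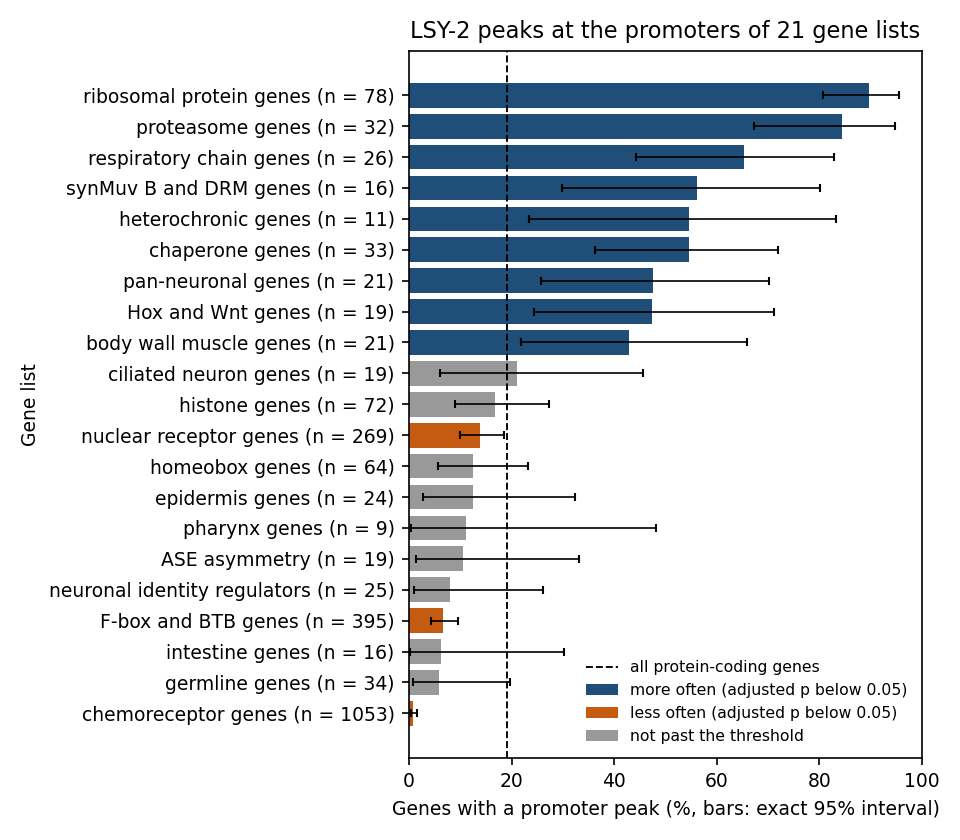
Share of genes with an LSY-2 promoter peak (horizontal, percent) in each of 21 gene lists (vertical), with exact 95% intervals and a dashed line at 19.2%, the share of all protein-coding genes. Ribosomal protein genes stood at 89.7% and chemoreceptor genes at 0.76%; blue and orange bars passed the test above and below other genes, and grey bars did not pass.

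The ASE genes were examined because LSY-2 is known from this cell pair. Of 19 protein-coding ASE asymmetry genes, 2 had a promoter peak, lsy-12 with a score of 294 and the Groucho gene unc-37 with a score of 242 (odds ratio 0.602, Fisher adjusted p = 0.69). No optimal summit lay in the promoters of lsy-2, lsy-6, cog-1, die-1, lim-6, fozi-1, gcy-5 or gcy-7. The nearest optimal summit was 14473 bp from lsy-6 and 8117 bp from lim-6. The relaxed lists held no summit in the lsy-6 promoter in either replicate, and 1 in the die-1 promoter in replicate 2. The chromatin came from whole animals, in which the ASE pair is a small part of the cells, so a count of 0 describes these lists and is no measure of binding in ASE neurons. The promoter of unc-119, the rescue marker of the strain, held no optimal summit, although 2 lay within the gene.

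The region of lsy-2 itself was examined because the strain carries a transgene made from it. No optimal peak lay within 20000 bp of lsy-2, at chromosome X 2089704 to 2093256, where gene windows on X held a median of 2. Of 1000 such windows 20.9% held as few. Within 50000 bp there were 2 peaks.

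Across all gene name classes, 19 had promoter peaks more often than other genes and 48 less often, of 123 tested. Translation initiation factor genes (eif) had a peak in 20 of 25 cases (Fisher adjusted p = 1.74e-09), mitochondrial ribosomal genes in 24 of 42 (mrpl, adjusted p = 7.43e-07) and 18 of 29 (mrps, adjusted p = 4.38e-06) and nuclear pore genes (npp) in 17 of 26 (adjusted p = 3.37e-06). Vacuolar protein sorting genes (vps) had a peak in 20 of 33 cases (Fisher adjusted p = 2.28e-06). Among the classes with fewer peaks were C-type lectins (clec, 4 of 239, Fisher adjusted p = 1.26e-15), collagens (col, 10 of 156, adjusted p = 5e-05), cytochromes P450 (cyp, 2 of 74, adjusted p = 0.000182) and neuropeptide-like proteins (nlp, 3 of 78, adjusted p = 0.000498). None of 193 str chemoreceptor genes had a peak. Taking 3 counts as the upper limit for a count of 0 allows a share of up to 1.55%, which is an approximate limit and not an exact interval.

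Genes for small structured RNAs were also near LSY-2 summits. A summit lay within 200 bp of 187 of 612 tRNA genes (30.6%, against 2.87% by chance), 91 of 346 snoRNA genes (26.3%, against 3.47%) and 25 of 129 snRNA genes (19.4%, against 3.09%). Genes annotated as ncRNA (13.2%, against 3.28%) and lincRNA (16.0%, against 9.03%) were also above chance. Pseudogenes (1.27%, against 9.25%) and piRNA genes (0.417%, against 2.28%) were below it. Each of these 7 gene types had an adjusted permutation p of 0.00257, and 2 others, microRNA genes (4.21%, against 3.05%, adjusted p = 0.438) and antisense RNA genes (7.0%, against 7.55%, adjusted p = 1), did not pass.

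The sequence at summits was richer in GC than the flanks, with 43.99% against 35.2%. Of 2080 6-mers, 810 were more frequent within 50 bp of summits than in the flanks and 594 less frequent. How many of these calls follow from the difference in GC was not tested. GAGAGA was in 27.1% of summit windows and 6.4% of flanks (exact McNemar test, adjusted p = 1.56e-212), and ACGCAG in 14.6% and 1.74% (exact test, adjusted p = 1.22e-164). AAAATT was in 19.6% of summit windows and 42.98% of flanks (exact test, adjusted p = 2.69e-173). The 6-mer ACCGTA, singled out after its values were seen, was in 6.88% of summit windows and 3.04% of flanks (exact test, adjusted p = 1.39e-22). It was in 32.5% of the strongest 10% of peaks (95% interval 28.8 to 36.3), in 5.86% of the next 10% and in 2.69% of the weakest 10%. In the strongest 10% it was the 6-mer with the lowest p (1.3e-47). GAGAGA was in 19.8% of the strongest 10%, with its highest share, 36.1%, in the seventh of the 10 groups.

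**Figure D4:**
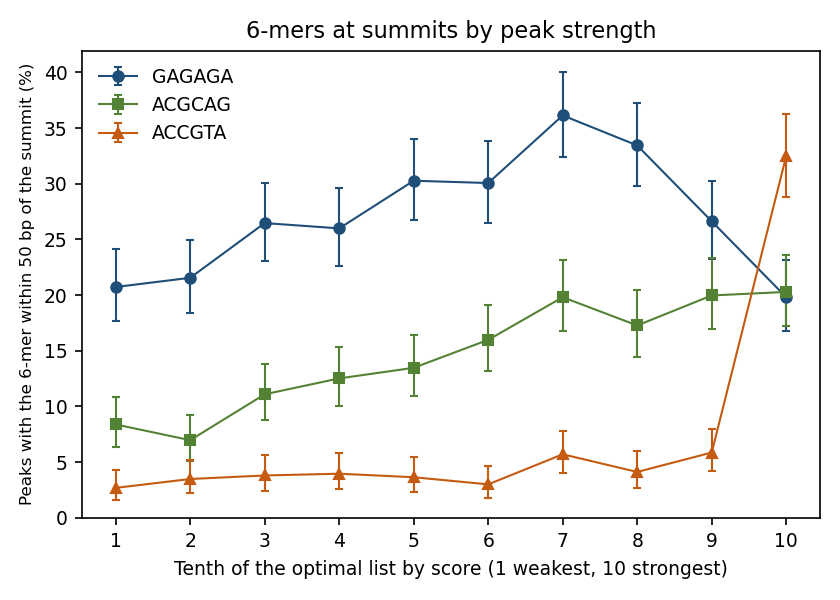
Share of peaks (vertical, percent) with each of 3 6-mers within 50 bp of the summit, in 10 groups of optimal peaks from weakest to strongest by score (horizontal); bars are exact 95% intervals. ACCGTA was between 2.69% and 5.86% in the 9 weaker groups and 32.5% in the strongest.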

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

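The every-transcript 5′ end and the pooled relaxed list near lsy-2 were alternatives chosen after seeing the data. The strongest pooled peaks are the same peaks as the optimal list, so that alternative tested nothing and is not counted here. Of 62 alternative values for the 12 main results, 59 kept their direction and side of the threshold or, without a test, stayed within 1.5 times (counts) or the 95% interval (the correlation). The peak count fell from 6312 to 5004 with peaks among the strongest of both replicates. The exceptions were the correlation of scores between replicates, which was 0.906 with the strongest 50% of each list and 0.779 with the whole relaxed lists, and the X share of 15.8%, which lay below the share of length and above the share of genes. The lower correlation came with 16957 matched peaks in place of 4989; the cause was not tested. The number of gene lists passing ranged from 9 to 13 of 21. Taken list by list, 11 of 168 alternatives lost a call and 2 gained one, and no list changed direction past the threshold. The promoter share ranged from 39.1% with the narrower window, against 11.1% by chance, to 61.6% with the strongest 50% of peaks. The 70 named genes with a promoter peak include pairs that share a peak, such as nra-2 and lin-53. All but prg-1 had their peak among the 6312 strongest of replicate 2, and all but nhr-25 among those of replicate 1. Of 201 alternative score ranks of the named peaks, 164 were counted as the same and 37 as moved. The X share on ce10 was not run, because no ce10 genome was used here. A highest percentile near lsy-2 could not be given with 0 peaks there, so the number of peaks was used. What depth limits could not be tested, since it is unknown here.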

Other observations

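The tests of what lies behind the ACCGTA share, those that use ACCGTA at ribosomal promoters and those of gaps around lsy-2 were chosen after the 6-mer scan and the count of peaks near lsy-2, both planned, had been seen. The comparison with the nearest peaks in rank was added after the difference of 17.8 points at ribosomal promoters had been seen, and the test of gene spacing was planned. Peaks near tRNA genes were of middling strength. Of 177 such peaks, 1 was in the strongest 10% of the list, and their median score was 114, at a median percentile of 46.3. Peaks near snRNA genes had a higher median score, 214, with 10 of 35 in the strongest 10%. Differences in score between these gene types were not tested. Peaks near pseudogenes were few, 30, but had a median score of 233. Of the tRNA gene peaks, 20.9% were also in the promoter of a protein-coding gene, against 42.9% of those near snRNA genes.

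ACCGTA at the strong peaks was weighed against base composition and location. On chromosomes I, III and V alone it was again the 6-mer with the lowest p in the strongest 10%, and on II, IV and X, which took no part in that choice, it was in 82 of 266 such peaks (30.8%, 95% interval 25.3 to 36.8), against 2.64% ± 1.00 (SD over 1000 shuffles) in the same windows shuffled with their dinucleotides kept, which argues against base composition. Among promoter peaks alone it rose from 2.0% in the weakest 20% of the list to 21.8% in the strongest 20%. The difference was 19.8 points (95% interval 16.7 to 22.7), which argues against a higher share of strong peaks in promoter windows as the whole cause. Distance from the 5′ end within the window was not matched, so an effect of closer location stays open. The rule set beforehand did not include the comparison among promoter peaks and rested on peaks outside promoters. There the difference was 7.41 points (95% interval 4.05 to 11.5), short of the bound of 10 set before it was computed. Of 270 ACCGTA sites within 250 bp of the strongest summits, 78.9% lay within 50 bp, but ACCGTA was chosen for its frequency there, so this says nothing about the cause. Whether ACCGTA is part of a sequence that recruits the tagged protein or a partner stays open.

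The absence of peaks around lsy-2 was weighed as chance or as an effect of the transgene. On X, 290 of 2731 protein-coding genes (10.6%) had no pooled relaxed summit within 20000 bp, so such a gap may be chance. The gap between pooled relaxed summits around lsy-2 was 48552 bp long, and 24.5% of X genes lay in gaps as long, while the gap in the optimal list was 174055 bp long, and 99 of 2731 X genes (3.63%) lay in gaps as long as that. Extra copies of the region in the control library could also remove peaks there, and this cannot be told apart from chance because the control reads were not analysed here.

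Peaks at ribosomal protein promoters were weighed against gene spacing and against a general recovery of active promoters. With the distance to the next gene upstream in a logistic model the odds ratio was 37.5, and with each peak given to its nearest 5′ end only it was 6.60 in place of 35.6, so part of the count came from peaks nearer to another gene, while both values argue against spacing as the whole cause. ACCGTA was in 47.1% of the 68 ribosomal promoter peaks, 17.8 points above other promoter peaks drawn from the same 10% groups of score, which met the bound of 10 set against general recovery. That comparison was too coarse, since 58 of the 68 peaks were in the strongest 10% and the median rank of the 68 was 178. Other promoter peaks nearest in rank carried ACCGTA in 47.7% (95% range 41.2 to 54.4). That range covers only repeated draws from the 10 nearest peaks of each ribosomal peak, not the sampling of peaks. The ACCGTA share itself rose with score, so neither comparison decides, a general recovery of active promoters stays open, and no biological explanation was tested, since there is no second group and no other factor to set beside this one.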
